A study of Mus musculus with 12 samples.

How the data were processed

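Polysome-bound mRNA, the mRNA that sediments with several ribosomes and is taken as being translated, was measured in mouse oocytes on 12 Affymetrix arrays. Per the labels' protocols, mice received PMSG, a hormone that makes follicles grow, and 48 h later hCG, which stands in for the ovulatory hormone surge. Oocytes were collected at hCG 0 h as germinal vesicle (GV) oocytes, which are arrested in meiotic prophase, and at hCG 14 h as metaphase II (MII) oocytes, which are mature eggs. The arrays fall into 4 groups of 3 by the sample titles: wild type at GV, wild type at MII, and oocytes from mice without amphiregulin (Areg) at the same stages. The strain label names C57BL/6J and 129Sv together for both genotypes. The titles call the arrays of a group biological replicates and the series' design text speaks of 3 independent sample sets. How many animals or oocytes a sample holds is not given in the sources used here, so the p values measure the spread between these samples.

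Per the labels' protocols, RNA from the polysome fraction was purified with a Qiagen RNeasy Plus Micro kit, amplified with a NuGEN WT-Ovation kit, biotin labelled and hybridised. The deposited values are log2 intensities, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes (its version and options are not given in the sources used here). RMA corrects background, applies quantile normalisation between arrays and summarises the probes of a set, so a change is measured relative to the other transcripts on the array, and a rise or fall of all polysome-bound mRNA together would not be seen. The labels disagree on the material: the molecule field of every sample names total RNA, while source name and protocol name polysome-bound transcripts, which is how the values are read here. The description fields, which speak of embryos, do not match oocytes and were not used. No separate array of unfractionated RNA was used here, so a change in polysome-bound mRNA may come from ribosome loading or from the amount of the transcript. The columns were matched to samples by their labels, and 0 per-sample columns were left unused.

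The table held 23950 probe sets, of which 64 were array controls and 23886 were named by a RefSeq transcript. Such names mean that a probe set definition other than the manufacturer's was used, and which release is not given in the sources used here. Transcripts were matched to gene symbols through a RefSeq table of the assembly GRCm38.p6, which served for names and gene order alone. Of the RefSeq probe sets, 21230 matched 1 symbol, 0 matched several and 2656 matched none, 2242 of these being predicted transcripts. The probe sets without a symbol and the controls were left out of the gene tests. For the 3019 genes with more than 1 probe set the one with the highest mean over all arrays was used, which left 16579 genes, all of which were tested. Array medians lay between 5.61 and 5.79, and no array pair held identical values. There is no detection call in the table, and the number of arrays limits the precision.

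All 12 arrays entered a single limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes without trend) with a mean per group, so that the 4 groups shared an estimate of the spread. The contrasts were MII minus GV in wild type, MII minus GV in the knockout, knockout minus wild type at GV and at MII, and the interaction, which is the knockout's stage change minus the wild type's. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all genes, and a gene was counted when its adjusted p was under 0.05. Errors are limma's standard errors (SE) on the log2 scale unless a standard deviation (SD) is named, and brackets hold 95% confidence intervals.

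Before the data were examined, 15 gene lists, 6 genes to report in every comparison and the alternatives were fixed. The lists were cyclin, CDK and APC/C regulation, spindle and kinetochore, mRNA translation and decay control, zona pellucida and oocyte-secreted factors, maternal-effect and reprogramming factors, meiotic chromosome axis, cohesin and recombination, DNA replication licensing and elongation, the PI3K-AKT-mTOR pathway, EGF ligands and receptors, cumulus and granulosa cell markers, blood, endothelial, theca and stromal markers, cytosolic ribosomal proteins, oxidative phosphorylation subunits, proteasome subunits and mitochondrial ribosomal proteins. The last 4 were defined by symbol pattern, which also takes in Rps27l, Psmb8 and Psmb11. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over all 75 list tests, and again with the correlation estimated from the data. At the preset value 20 of the 75 tests passed, and with the estimated correlation 10 did, the falls of 5 lists from GV to MII in each genotype. The lists were also tested with limma's fry, adjusted over the same tests. Members were also counted with p values adjusted over the list alone. The genes that rose or fell with stage in the mean of both genotypes were tested as sets on the interaction with limma's fry, which asks whether a set's genes move one way on balance.

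The genes named are, per comparison, the 10 largest rises and 10 largest falls past the threshold whose groups of arrays did not overlap (chance gives 10% for 3 arrays against 3), leaving out clone names and predicted genes. Where fewer than 3 genes passed in a direction, the 5 with the smallest p are named and said not to pass. For each list described the members with the smallest p are named, and Areg, Tpx2, Dazl, Il7, Ccnb1 and Mos are always named. The values of a few genes that this rule selects are not reported here.

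The fits were tested on simulated data with the real genes' means and spreads and 200 changed genes, 50 of each size. For the stage change in wild type, 12% of genes changed by 1 on the log2 scale were recovered, 46% of those changed by 2, 76% by 3 and 86% by 4, with 4.35% false among the calls. For the genotype difference at MII the shares were 10%, 60%, 86% and 88%, with 6.15% false. For the interaction they were 2%, 36%, 70% and 74%, with 4.21% false. The simulated noise was drawn for each gene on its own, so the false shares do not cover structure shared by arrays. The real stage change in wild type counted 3574 genes, far more than the 200 changed here. With more changed genes the Benjamini-Hochberg adjustment accepts larger p values, so the shares for stage do not measure the power of the real test. The real tests counted 10 genes for genotype at MII and 0 for the interaction. With fewer changed genes the adjustment is stricter, so the shares for these 2 comparisons may overstate the power.

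The alternatives were centring each array on its median, a further quantile normalisation, a filter on dim genes, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust, array weights, a fit of the compared groups alone, the replicate number as a block, a minimum log2 change of 1, and leaving out each array. Added after seeing the data were the interquartile range of each array's values as a covariate, a fit without the 4 arrays with the narrowest range at their stage (wild-type GV 3, wild-type MII 2, knockout MII 2 and knockout MII 3), the genotype difference averaged over the stages, and the median centring and quantile normalisation for the lists. The fit without those 4 arrays keeps 1 knockout MII array, so its comparisons with that group rest on a single array there.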

Results

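Polysome-bound mRNA was profiled in GV and MII oocytes of wild-type mice and of mice without amphiregulin, an EGF-family ligand that granulosa cells release after the ovulatory hormone surge. The series title asks whether the translational program of the oocyte differs between the genotypes. Each of the 4 groups held 3 arrays, and 16579 genes were measured. Stage was the largest difference among the arrays. Pearson correlations across genes were 0.950 to 0.976 within a GV group and 0.920 to 0.949 within an MII group. Between genotypes at the same stage they were 0.943 to 0.973 at GV and 0.919 to 0.952 at MII, and between stages 0.819 to 0.867. The first principal component held 56.1% of the variance and the second 9.67%.

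The arrays differed in the spread of their values. The interquartile range of log2 values was 4.37 ± 0.34 in wild-type GV, 3.81 ± 0.32 in wild-type MII, 4.54 ± 0.14 in knockout GV and 3.57 ± 0.36 in knockout MII (SD, n = 3 arrays). The lowest values at MII belonged to wild-type MII 2 (3.45), knockout MII 2 (3.35) and knockout MII 3 (3.37). The 3' minus 5' signal of the Gapdh control probe sets, a sign of RNA integrity and priming, was 2.00 ± 0.31 in wild-type GV, 3.23 ± 0.48 in wild-type MII, 2.48 ± 0.75 in knockout GV and 2.71 ± 0.61 in knockout MII. For Actb it was 0.36 ± 0.81, -1.17 ± 0.18, 0.05 ± 0.56 and -0.77 ± 0.37 in the same order. The lists of markers of other cell types had low medians. Those of the cumulus and granulosa markers, the cells that surround the oocyte, lay at 4.81, 4.67, 4.63 and 4.80 in the same order, the 35.9th percentile of all genes. Those of the blood, endothelial, theca and stromal markers lay at the 30.6th percentile, whereas Pecam1, a member of that list, had group means of 9.52, 11.11, 8.58 and 9.06. Zona pellucida and oocyte-secreted factors lay at the 98.96th and maternal-effect factors at the 98.4th.

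Areg, the targeted gene, was close to the lowest values of the arrays in every group. Its means were 2.36 ± 0.31 in wild-type GV, 2.72 ± 0.20 in wild-type MII, 2.49 ± 0.10 in knockout GV and 2.68 ± 0.31 in knockout MII (log2, SD, n = 3). Knockout minus wild type was 0.13 [-0.41, 0.67] at GV and -0.04 [-0.58, 0.50] at MII, and neither passed the limma test (adjusted p = 1.0 and 0.99). With the transcript near the floor in wild-type oocytes, the arrays could not check the genotype labels.

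Of the other genes fixed in advance, Dazl, Il7, Ccnb1 and Mos rose with maturation in both genotypes. Dazl, an RNA-binding translational regulator of germ cells, rose by 1.80 ± 0.21 on the log2 scale in wild type and 1.77 ± 0.21 in the knockout (SE, n = 3 arrays per group). Il7, a cytokine, rose by 2.67 ± 0.38 and 2.64 ± 0.38. Ccnb1, the cyclin partner of Cdk1, rose by 2.14 ± 0.26 and 2.09 ± 0.26, and Mos, the kinase behind MII arrest, by 1.35 ± 0.27 and 1.46 ± 0.27. The adjusted p of these 4 genes lay between 1.9e-04 and 0.0044. Tpx2, a spindle assembly factor, was 0.60 ± 0.30 and 0.68 ± 0.30 higher at MII without passing (adjusted p = 0.18 and 0.10). In the knockout Tpx2 passed after a further quantile normalisation, at 1.09.

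**Figure D1:**
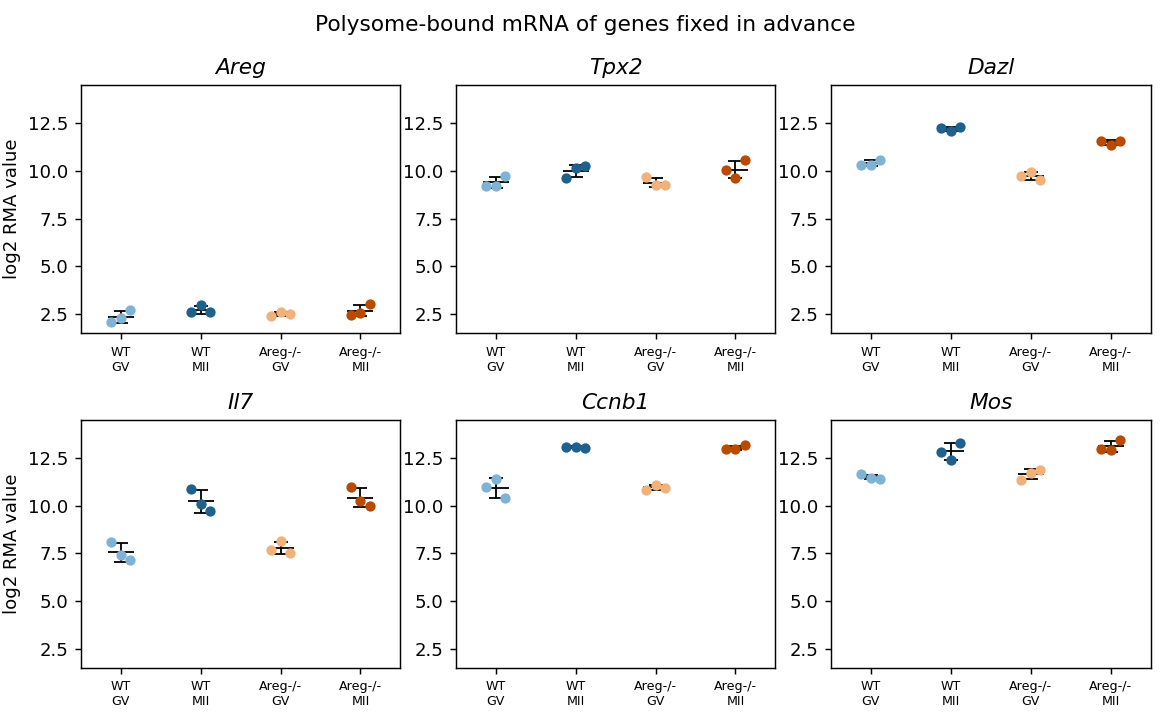
Log2 RMA values of polysome-bound mRNA for the 6 genes fixed in advance, with 1 point per array, the bar at the mean of 3 arrays and whiskers of 1 SD. Dazl, Il7, Ccnb1 and Mos lie higher at MII than at GV in both genotypes, Tpx2 did not pass the test, and Areg lies between 2.08 and 3.03 on every array.

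From GV to MII in wild type, the genes with the largest gains in polysome-bound mRNA had varied functions. Grb7, an adaptor of receptor tyrosine kinases, rose by 5.59 ± 1.04 on the log2 scale, 48.1-fold (SE, n = 3 arrays per group). Zfp449 rose by 4.68 ± 0.49, Efcab7 by 4.22 ± 0.51, the cohesin subunit gene Stag1 by 4.10 ± 0.56 and the lysosomal membrane protein gene Lamp2 by 4.09 ± 0.56. Slc6a15 (4.02 ± 0.46), Tmtc3 (3.98 ± 0.34), Fam172a (3.94 ± 0.71) and the prenyltransferase subunit gene Pggt1b (3.92 ± 0.52) followed. Slc3a1, an amino acid transporter subunit, rose by 4.12 ± 1.15, but its call was lost without any of wild-type GV 2, GV 3, MII 2 or MII 3.

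The genes with the largest losses included subunits of respiratory complex I and ribosomal proteins. Ndufv3, a subunit of respiratory complex I, fell by 7.69 ± 0.58, 206-fold. The complex I genes Ndufa3 (-6.61 ± 1.20) and Ndufa7 (-5.71 ± 0.87) fell, and the proton pump gene Atp6v1f fell by 7.41 ± 0.75. Of ribosomal protein genes, Rpl26 fell by 6.43 ± 0.54, Rps9 fell by 5.91 ± 0.70 and the mitochondrial Mrpl33 fell by 6.35 ± 0.95. Naa38 (-5.94 ± 0.59), Snx17 (-5.92 ± 0.61) and Ssr2 (-5.85 ± 0.82) fell as well. The adjusted p of these 20 named genes lay between 3.3e-05 and 0.025. Over all genes, limma counted 3574 changed, 1487 higher and 2087 lower at MII. The balance of directions turned after a further quantile normalisation (1903 higher and 1788 lower) and with the array spread as a covariate (1624 and 1490). The median change of all genes was 0.20.

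In wild type 5 lists fell by the camera test, though not every member did, between stages that differed too in array spread and in the 3' minus 5' signals of Actb and Gapdh. Of 73 measured subunits of oxidative phosphorylation, 60 fell and 0 rose, with a median of -3.42 (Ndufb8 -4.37, Ndufc2 -3.42, Cox6a1 -2.54). Of 70 mitochondrial ribosomal proteins, 43 fell and 1 rose (median -2.01, Mrps18c -5.42, Mrps28 -3.83, Mrps6 -4.16). Of 28 cytosolic ribosomal proteins, 17 fell and 0 rose (median -2.83, Rps24 -3.91, Rpl14 -3.26). Of 34 proteasome subunits, 21 fell and 1 rose (median -1.60, Psmd6 -4.42, Psma6 -3.10, Psmb4 -3.90). Of 19 zona pellucida and oocyte-secreted factors, 11 fell and 3 rose (median -1.34). Among them the oocyte transcription factors Figla (-4.85) and Nobox (-3.02) fell, and the zona protein gene Zp1 fell by 2.01. Adjusted over the list alone, the higher and lower counts were 0 and 65, 1 and 48, 1 and 18, 2 and 21, and 3 and 11 in this order. The camera test gave adjusted p = 9.7e-35, 1.0e-18, 2.0e-11, 2.9e-08 and 2.7e-04. With an estimated correlation the adjusted p was 5.5e-04, 2.7e-04, 0.0020, 0.0020 and 0.034, so all 5 calls held. Among the 8685 genes above the median brightness alone, the call of the zona and oocyte-secreted list was lost (adjusted p = 0.081).

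None of the other lists passed the camera test in wild type, and all but the EGF list held members that rose and members that fell. By limma's fry, which does not compare a list with other genes, EGF ligands and receptors and mRNA translation and decay control moved up on balance (adjusted p = 0.013 for both). The EGF list was dim, at the 31.3th percentile of all genes. The lower quartile of an array's values lay at 3.93 to 4.18 in wild-type GV and at 4.11 to 4.36 in wild-type MII. The fry test cannot tell a gain of the EGF list from such a lift of dim values. Of 28 cyclin, CDK and APC/C genes, 11 rose and 5 fell (adjusted over the list alone, 11 and 6; list adjusted p = 0.69). Cdk1 fell by 4.37 ± 0.36, while the spindle checkpoint gene Bub1b rose by 1.49 ± 0.21 and the kinase gene Wee2, which restrains Cdk1, by 1.59 ± 0.23. Of 29 spindle and kinetochore genes, 10 rose and 5 fell (11 and 5; 0.26). The motor gene Kif11 rose by 2.20 ± 0.23, while Birc5 fell by 3.33 ± 0.32, Tacc3 fell by 2.65 ± 0.28 and Spc24 fell by 4.19 ± 0.51. Of 26 genes of mRNA translation and decay control, 7 rose and 6 fell (10 and 6; 0.48). Pan2, a subunit of a poly(A) nuclease, rose by 2.71 ± 0.26, while Cpeb1, a regulator of cytoplasmic polyadenylation, fell by 2.28 ± 0.24 and Eif4enif1 fell by 1.77 ± 0.21.

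Of 25 maternal-effect and reprogramming factors, 6 rose and 4 fell (adjusted over the list alone, 7 and 10; list adjusted p = 0.54), among them Kdm1a (1.68), Rlim (1.90), Khdc3 (-2.78) and Padi6 (-2.19). Of 20 genes of the meiotic chromosome axis and recombination, 4 rose and 3 fell (4 and 4; 0.89), among them Tex19.1 (1.57) and Syce2 (-1.29). Of 29 DNA replication genes, 10 rose and 6 fell (10 and 9; 0.94), among them the origin recognition gene Orc6 (2.72), Cdc45 (2.55), the helicase gene Mcm4 (2.03) and Rpa2 (-4.74). The median of this list was 0.13 and its mean -0.02. Of 25 genes of the PI3K-AKT-mTOR pathway, 5 rose and 1 fell (5 and 1; 0.56), among them the mTOR inhibitor gene Deptor (3.04), Eif4ebp2 (2.26) and Rps6ka1 (-2.99). Of 14 EGF ligands and receptors, 3 rose and 0 fell (3 and 0; 0.096), namely Egf (2.33), Errfi1 (1.51) and Adam17 (0.93), whose call was lost without any of wild-type GV 2, GV 3, MII 1 or MII 3. Of 26 cumulus and granulosa markers, 2 rose and 1 fell (2 and 1; 0.96): Serpine2 (1.19), Cyp19a1 (2.13) and Hsd17b1 (-2.85), with a list median of 0.08 and mean of -0.05. Of 16 blood, endothelial, theca and stromal markers, 1 rose and 1 fell (1 and 1; 0.65): C1qb (-2.68) and Pecam1 (1.59), whose call was lost with the array spread as a covariate (1.04).

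In knockout oocytes the same comparison gave a similar set of gains and losses. The cell polarity kinase gene Prkci rose by 4.20 ± 0.47, Zfp708 by 3.97 ± 0.48, Lamp2 by 3.88 ± 0.56, Lnpep by 3.78 ± 0.62 and the protease gene Mbtps2 by 3.65 ± 0.51 (SE, n = 3 arrays per group). Scrn3 (3.83 ± 0.81), Prrg1 (3.72 ± 0.39) and Rsbn1 (3.59 ± 0.53) also rose. Nxt2 rose by 3.91 ± 1.07, a call lost without any of knockout GV 2, GV 3 or MII 1, and Lekr1 by 3.59 ± 0.63. Rpl26 fell by 6.73 ± 0.54, Ndufv3 fell by 6.68 ± 0.58 and Snx17 fell by 6.63 ± 0.61. The complex I genes Ndufa9 (-6.39 ± 0.51) and Ndufb5 (-6.29 ± 0.67) fell, and the actin-binding gene Pfn2 fell by 6.35 ± 0.54. Fam47e (-6.78 ± 0.86), Malsu1 (-6.50 ± 0.84), the proton pump gene Atp6v1e1 (-6.34 ± 0.86) and Mrpl33 (-6.14 ± 0.95) were also lower. With the array spread as a covariate the calls of Lekr1, Fam47e, Atp6v1e1 and Mrpl33 were lost (1.84, -4.58, -5.16 and -5.42). Over all genes limma counted 4672 changed, 2150 higher and 2522 lower. The balance turned after a further quantile normalisation (2326 higher and 1977 lower), with array weights (3155 and 2788), without knockout MII 1 (2583 and 2507) and with the spread covariate (939 and 838). The count was 2882 without knockout GV 1, 3029 without knockout GV 2 and 1777 with the spread as a covariate. A further quantile normalisation moved the median change of all genes by -0.16 in the knockout and -0.09 in wild type, and changes are relative to such a shift.

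The 5 lists that fell in wild type also fell in the knockout, between stages that differed too in array spread and in the 3' minus 5' signal of Actb. Of the oxidative phosphorylation subunits 63 fell and 0 rose (median -3.48, Ndufs7 -5.64, Sdhd -4.25, Ndufa8 -4.04). Of the mitochondrial ribosomal proteins 51 fell and 2 rose (median -2.23, Mrps18c -5.52, Mrpl58 -4.52), of the cytosolic ribosomal proteins 18 fell and 0 rose (median -2.26, Rps24 -4.27, Rpl14 -3.63), and of the proteasome subunits 19 fell and 2 rose (median -1.77, Psma6 -3.89, Psmd6 -4.23). Of the zona and oocyte-secreted factors 10 fell and 4 rose (median -1.57), among them Figla (-5.56), Nobox (-4.06), Zp1 (-1.90) and the gap junction gene Gja4 (-2.26). Adjusted over the list alone, the higher and lower counts were 0 and 63, 2 and 53, 0 and 18, 3 and 21, and 4 and 11 in this order. The camera test gave adjusted p = 3.6e-32, 6.6e-19, 4.1e-11, 1.6e-07 and 6.3e-04, and with an estimated correlation the adjusted p was 5.7e-04, 2.7e-04, 0.0020, 0.0024 and 0.041. Among genes above the median brightness alone, the call of the zona and oocyte-secreted list was lost (adjusted p = 0.17).

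None of the remaining lists passed the camera test in the knockout, and all but the EGF list held members that rose and members that fell. By limma's fry, mRNA translation and decay control (adjusted p = 0.0073) and EGF ligands and receptors (0.013) moved up on balance and maternal-effect factors moved down (0.026). For the dim EGF list a lift of dim values again cannot be told apart from a gain. The lower quartile of an array's values lay at 3.88 to 3.99 in knockout GV and at 4.15 to 4.41 in knockout MII. Among cyclin, CDK and APC/C genes 7 rose and 8 fell (adjusted over the list alone, 9 and 10; list adjusted p = 0.54): Cdk1 fell by 4.15 ± 0.36, the phosphatase gene Cdc25b fell by 4.11 ± 0.45 and the APC/C activator gene Cdc20 rose by 2.25 ± 0.30. Among spindle and kinetochore genes 10 rose and 6 fell (10 and 6; 0.93), with Prc1 up by 2.34 ± 0.27 and Birc5, Tacc3 and Spc24 at -3.53, -2.91 and -4.53. Among genes of mRNA translation and decay control 9 rose and 6 fell (11 and 6; 0.40), including Pan2 (2.29), Dcp1a (1.99) and Eif4enif1 (-1.89). Among maternal-effect factors 6 rose and 8 fell (6 and 10; 0.096), including Khdc3 (-3.48), Tle6 (-1.32), and Dnmt3l (-3.83) and Kdm1a (1.28), whose calls were lost with the spread covariate. Among meiotic genes 4 rose and 4 fell (4 and 4; 0.89), including Tex19.1 (1.71) and Syce2 (-1.45), with a list median of 0.29 against a mean of -0.32. Among DNA replication genes 8 rose and 10 fell (10 and 11; 0.54), including Rpa2 (-4.82), Orc6 (2.30) and Cdc45 (2.26). In the PI3K-AKT-mTOR pathway 3 rose and 3 fell (3 and 3; 0.90), and the median of 0.20 went against the direction of the test. Rps6ka1 (-2.40) and Tsc2 (-2.52) in that list lost their calls with the spread covariate. Of the EGF list 0 rose and 0 fell (0 and 0; 0.12), with 14 genes short of the threshold, Errfi1 (0.95, adjusted p = 0.052) and Egf (1.13, 0.055) closest. Both passed after a further quantile normalisation (adjusted p = 0.0062 and 0.012), with array weights (0.045 and 0.044) and without wild-type MII 1. Errfi1 also passed in the compared groups alone, with the spread covariate and without wild-type MII 2, and Egf among bright genes and without knockout MII 1. Ereg and Btc, close to the lowest values of the arrays, passed with trend and robust (adjusted p = 0.045 and 0.039), Ereg also with array weights and without knockout MII 1, and Btc also without knockout MII 2. Among cumulus and granulosa markers 2 rose and 2 fell (2 and 2; 0.54), including Gja1 (-4.17), whose call was lost without the 4 arrays of narrowest spread, and Hsd17b1 (-2.39). Among blood, endothelial, theca and stromal markers 3 rose and 1 fell (1 and 1; 0.26), namely Emcn (1.18), Lyz2 (0.95), Acta2 (0.66) and C1qb (-2.88). With the spread covariate all 4 calls were lost, and Lyz2 turned to -0.036. Without the narrow arrays the 3 rises were lost. Emcn also lost its call without knockout GV 2, Acta2 without wild-type GV 1, wild-type GV 2 or any knockout array, and Lyz2 without wild-type GV 2, any wild-type MII array or any knockout array but MII 1.

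**Figure D2:**
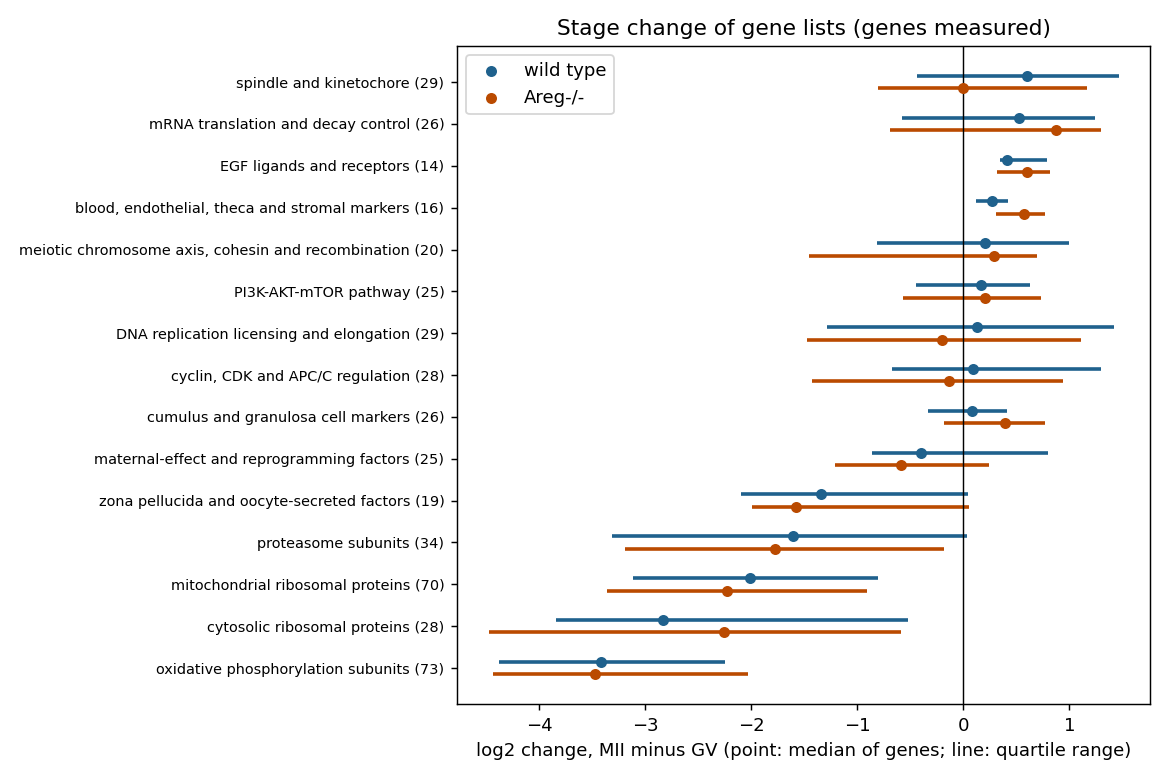
Median stage change (MII minus GV, log2) of the 15 gene lists in wild type (blue) and Areg knockout (orange) oocytes, with lines spanning the quartiles of the genes and the number of genes measured in brackets. Oxidative phosphorylation subunits lie lowest, at -3.42 and -3.48, and the 5 lists with the lowest medians are those that passed the camera test in both genotypes.

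The stage changes of the genotypes ran together gene by gene. Of the genes that rose in wild type, 944 also rose in the knockout, against 193 for independent lists, and of those that fell, 1753 also fell, against 317. A total of 4 genes, named here after their values were seen, rose in wild type and fell in the knockout: Ddx10 (1.44 and -1.39), Myh3 (1.37 and -1.03), Rhoh (1.38 and -1.27) and Trmt10c (1.46 and -1.50), none of which passed the interaction test. Of the genes changed in wild type 98.2% had the same sign in the knockout, and of those changed in the knockout 97.6% had the same sign in wild type. Across the 16579 genes, which are not independent replicates, the changes correlated at Pearson's r = 0.855 and Spearman's rho = 0.762. The comparisons share no arrays, though all arrays entered the same fit.

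**Figure D3:**
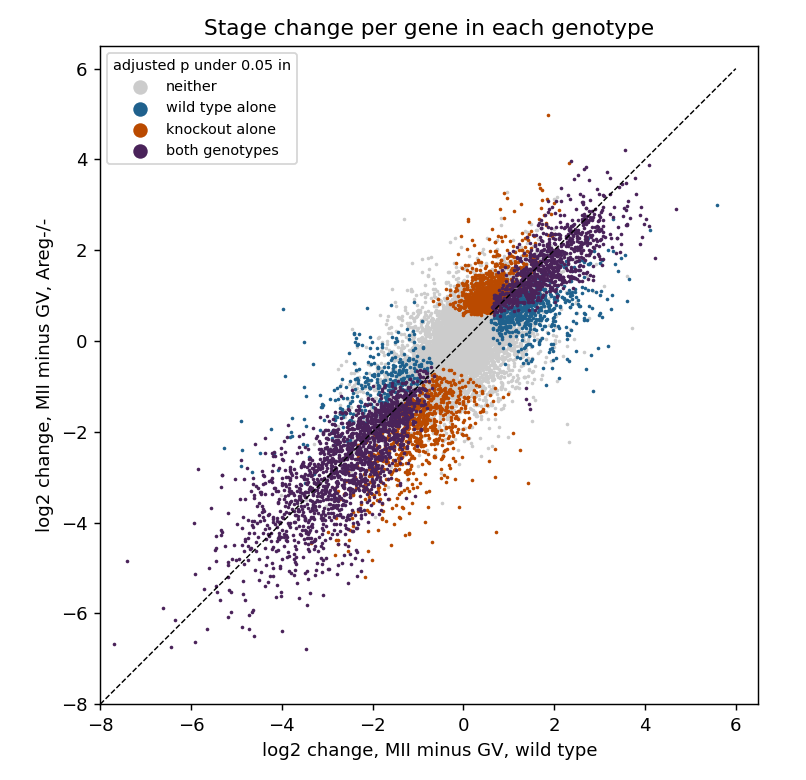
Stage change of each of 16579 genes (log2, MII minus GV) in wild type (x axis) and Areg knockout (y axis), coloured by whether the adjusted p was under 0.05 in neither genotype, wild type, the knockout or both, with the dashed line at equal change. The points follow the line, with r = 0.855 across genes.

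Before the hCG stimulus, knockout and wild-type GV oocytes were close. No gene passed, and the genes with the smallest p are given as values. Slc4a3, an anion exchanger, was 2.49 ± 0.32 higher in the knockout and Arid5b, a chromatin-associated factor, was -3.59 ± 0.44 (adjusted p = 0.063 for both; SE, n = 3 arrays per group). Snord104 (3.20), Nrm (1.298), Gas2l1 (2.03) and Defb8 (2.60) were the next on the higher side, and Uba6 (-2.26), Syt9 (-1.58) and Klhl30 (-2.51) on the lower side. Dazl was -0.66 [-1.12, -0.20], Tpx2 -0.01, Il7 0.21, Ccnb1 0.04 and Mos 0.15, each with an adjusted p of 1.0. The limma count was 0 genes, with 589 at an unadjusted p under 0.05 where chance gives 829. With array weights 17 genes passed, and 3 passed without knockout GV 3 and 1 without wild-type GV 1.

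Among the lists at GV, 2 passed the camera test with its preset correlation. The blood, endothelial, theca and stromal markers were lower in the knockout (median -0.25, adjusted p = 0.015), led by Pecam1 (-0.94) and Kdr (-1.55), and the oxidative phosphorylation subunits were higher (median 0.20, adjusted p = 0.024), led by Ndufs5 (1.23) and Atp5pb (1.303). Both calls were lost with an estimated correlation (adjusted p = 0.46 and 0.37), and also after a further quantile normalisation (adjusted p = 0.11 and 0.18). Without the 4 arrays of narrowest spread, of which wild-type GV 3 (3.97) is the only one at GV, the medians were -0.066 and 0.11 (adjusted p = 0.39 and 0.91), and with the spread covariate -0.14 and 0.13 (0.15 and 0.30). Neither list passed limma's fry (adjusted p = 0.32 and 0.40). In these 2 lists 0 members passed over all genes and 0 adjusted over the list alone. The first list lies at the 30.6th percentile of brightness. The other 13 lists did not pass, and 0 of their members passed over all genes or adjusted over the list alone.

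At MII, 10 genes differed between the genotypes in the fit of all arrays, 1 higher and 9 lower in the knockout. When the MII groups were fitted alone 0 passed. The balance of directions did not hold without the 4 arrays of narrowest spread, a fit that leaves 1 knockout MII array. Clybl, a mitochondrial enzyme gene, fell by 4.64 ± 0.60 relative to wild type, 24.9-fold (adjusted p = 0.027; SE, n = 3 arrays per group). Uba6, a ubiquitin-activating enzyme gene, fell by 3.68 ± 0.37 (0.012), Arid5b fell by 3.08 ± 0.44 (0.045) and Rbl2, of the retinoblastoma family, fell by 2.80 ± 0.40 (0.044). Uimc1, a DNA damage response gene, fell by 2.37 ± 0.31 (0.027), Fbxw13 fell by 2.10 ± 0.25 (0.018), the splicing factor gene Crnkl1 fell by 1.96 ± 0.21 (0.014), Tmem114 fell by 1.89 ± 0.28 (0.045) and the mitochondrial ribosome gene Mrpl58 fell by 1.81 ± 0.20 (0.014). Kif21a, a kinesin gene, was 2.12 ± 0.29 higher (0.041). Fgf16 (2.45, adjusted p = 0.051), Fcgbp (1.87), Ctif (2.64) and H2-Aa (2.58) were higher without passing, though Fgf16 passed after median centring (adjusted p = 0.038), after a further quantile normalisation (0.035), with the mean of probe sets (0.047), without knockout GV 2 and without knockout MII 1. Tpx2 (0.07), Il7 (0.19), Ccnb1 (-0.02), Mos (0.27) and Dazl (-0.69 [-1.14, -0.23], adjusted p = 0.48) did not pass.

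The profiles of these genes over the stages were of more than 1 kind. Uba6, Arid5b and Crnkl1 were lower in the knockout at GV too, at -2.26, -3.59 and -1.12, and passed in the mean of both stages, a comparison added after seeing the data. Clybl lay at 9.13 ± 0.92 at GV and 9.84 ± 1.27 at MII in wild type, and at 9.40 ± 0.33 and 5.20 ± 0.44 in the knockout (SD, n = 3). Its knockout MII mean lay below the array medians (5.61 to 5.79). Without a detection call that mean is not shown to be above background, so its fold difference is not exact. The same limit holds for Uba6 (4.34 at knockout MII and 4.73 at knockout GV), Rbl2 (4.94 at knockout MII) and Kif21a (4.84 at wild-type MII). Rbl2 lay at 4.48 ± 0.42 and 7.74 ± 0.61 in wild type and at 4.25 ± 0.50 and 4.94 ± 0.50 in the knockout. Uimc1, Fbxw13, Tmem114 and Mrpl58 were lower at MII in both genotypes, with Mrpl58 at 11.03 ± 0.24 and 8.49 ± 0.14 in wild type and 11.20 ± 0.02 and 6.69 ± 0.11 in the knockout. Over all genes 1024 had an unadjusted p under 0.05 where chance gives 829. With the replicate number as a block 0 genes passed, with a smallest adjusted p of 0.055. The count was 0 when the MII groups were fitted alone, with a smallest adjusted p of 0.47 by limma. Correlations within a group were higher at GV (0.950 to 0.976) than at MII (0.920 to 0.949). The 10 calls thus depend on the spread estimate shared with the GV arrays, which do not enter the difference itself. The count was 5 with a trend and robust fit and 16 after a further quantile normalisation. Most of the 10 calls were lost without the 4 arrays of narrowest spread, which leaves 1 knockout MII array. Leaving out an array gave 32 without knockout MII 1, 2 without wild-type MII 1, 3 without wild-type GV 1, wild-type GV 2, wild-type MII 3, knockout GV 1 or knockout MII 2, 5 without wild-type GV 3 or knockout MII 3, and 6 without knockout GV 3. Over up to 23 alternatives, Uba6 lost its call in 3, Crnkl1 in 6, Mrpl58 in 7, Fbxw13 in 9, Clybl in 10, Uimc1 in 14, Kif21a and Rbl2 in 15, Arid5b in 17 and Tmem114 in 18. Each kept its direction throughout. Ranges were, for example, -4.09 to -2.99 for Uba6, -4.02 to -2.70 for Arid5b, -2.15 to -1.76 for Tmem114 and 1.72 to 2.46 for Kif21a. The MII arrays of the genotypes did not overlap for any of these 10 genes, so leaving out arrays could not turn a direction. Several other alternatives reuse the same group means, so the kept directions are no independent support.

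**Figure D4:**
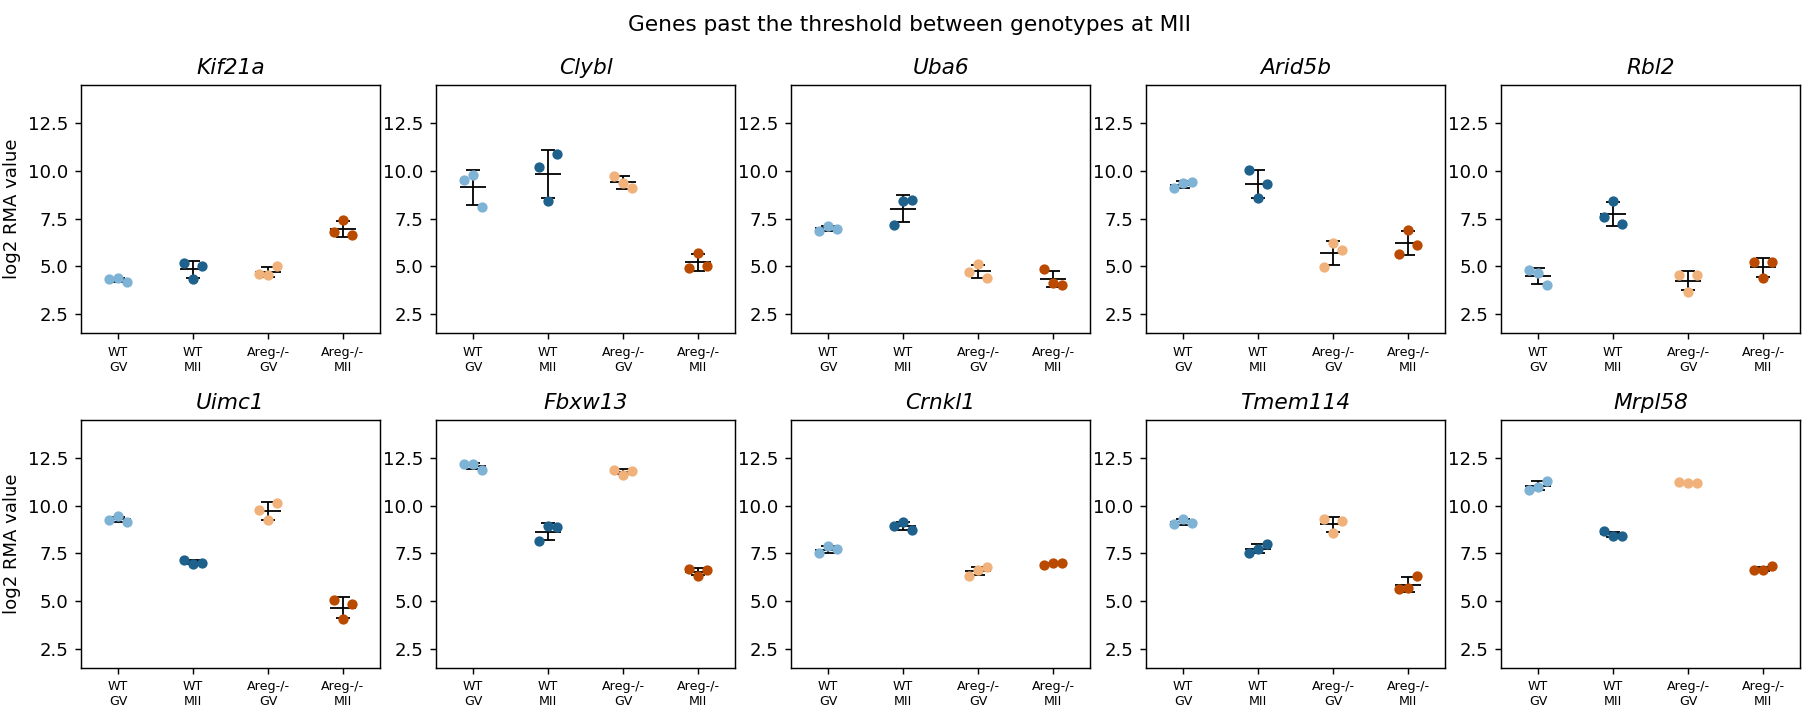
Log2 RMA values of the 10 genes past the threshold between genotypes at MII, with 1 point per array, the bar at the mean of 3 arrays and whiskers of 1 SD. Kif21a is higher and the other 9 genes are lower on the 3 knockout MII arrays, and Uba6, Arid5b and Crnkl1 are also lower on the knockout GV arrays.

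Of the lists at MII, 4 were lower in the knockout by the camera test with its preset correlation, and all 4 calls were lost with an estimated correlation (adjusted p = 0.30, 0.23, 0.43 and 0.19 in the order they are named next) and after a further quantile normalisation (adjusted p = 0.13, 0.13, 0.15 and 0.28). These were spindle and kinetochore genes (median -0.27, adjusted p = 0.0035), maternal-effect and reprogramming factors (-0.15, 0.0090), the PI3K-AKT-mTOR pathway (-0.18, 0.017) and cyclin, CDK and APC/C genes (-0.11, 0.021). The members with the smallest p were Kif11 (-0.65), Kif4 (-1.01) and Ndc80 (-0.99) in the first list, Tle6 (-0.47) and Dnmt3l (-1.19) in the second, Eif4ebp2 (-1.39) and Tsc2 (-1.56) in the third, and Cdc25b (-1.83), Ccnb3 (-2.38) and Plk1 (-1.42) in the fourth. None of the 4 lists passed limma's fry (adjusted p = 0.21, 0.12, 0.31 and 0.18 in the same order). In each of these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. Without the narrow arrays, which leaves 1 knockout MII array, the spindle median was 0.0057. The array spread was also lower in knockout MII (3.57 ± 0.36) than in wild-type MII (3.81 ± 0.32; SD, n = 3). The other 11 lists did not pass. In them Mrpl58 passed over all genes. Adjusted over the list alone, 1 mitochondrial ribosome gene (Mrpl58) and 1 blood and stromal marker (Pecam1, -2.05) were lower, while of the oxidative phosphorylation subunits 2 were higher, Ndufb8 (1.38) and Ndufs8 (1.69), and 2 lower, Ndufa9 (-2.44) and Cox5b (-1.79). Median, mean and test differed in sign for the zona, meiotic, EGF, blood and stromal, and proteasome lists, and at GV for the zona and EGF lists, all with an adjusted p of 0.85 or more.

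The interaction asked whether the change from GV to MII itself differed between the genotypes. No gene passed. The fixed genes gave small differences with wide intervals: Tpx2 0.08 [-0.84, 1.00], Dazl -0.03 [-0.67, 0.62], Il7 -0.02 [-1.21, 1.17], Ccnb1 -0.05 [-0.85, 0.74], Mos 0.12 [-0.72, 0.96] and Areg -0.17 [-0.93, 0.59]. The smallest adjusted p was 0.27, shared by Mrpl58 (-1.98 ± 0.29), the nuclear envelope gene Nrm (-1.97 ± 0.30) and Uimc1 (-2.81 ± 0.44). Reep6 (-3.97) and Clybl (-4.91) were next on that side, and Syt9 (2.38), Klhl30 (3.49), Fgf16 (2.59), Ctif (3.16) and Ppp1r1a (1.42) on the other. The limma count was 0, with 772 genes at an unadjusted p under 0.05 where chance gives 829. Without knockout MII 1 or knockout MII 3, 1 gene passed.

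The genes that moved with stage were also compared as sets. The 4002 genes that rose in the mean of both genotypes had a median change of 0.78 in wild type and 0.92 in the knockout, a median interaction of 0.10. The 3313 genes that fell had medians of -1.82 and -1.99, a median interaction of -0.18. Neither set's interaction passed limma's fry at 0.05. The rising set's interaction turned to -0.13 among bright genes and to -0.029 without wild-type MII 2, and the falling set's (-0.24) passed with the spread covariate. By the camera test at its preset correlation, 4 lists had a lower change in the knockout: spindle and kinetochore genes (median interaction -0.33, adjusted p = 0.0022), cyclin, CDK and APC/C genes (-0.26, 0.0090), maternal-effect factors (-0.22, 0.021) and DNA replication genes (-0.43, 0.027). All 4 calls were lost with an estimated correlation (adjusted p = 0.29, 0.13, 0.30 and 0.46) and after a further quantile normalisation (adjusted p = 0.15, 0.26, 0.39 and 0.57). They were also lost with the spread covariate, where the cyclin median was -0.0029, and without the narrow arrays, where the DNA replication median turned to 0.021 and the spindle median was -0.12. Examples are Kif11 (-1.03 ± 0.32), Wee2 (-0.91 ± 0.32), Khdc3 (-0.70 ± 0.48) and Mcm4 (-0.92 ± 0.36), none of which passed alone. None of the 4 lists passed limma's fry (adjusted p = 0.21, 0.16, 0.21 and 0.40 in the same order). In each of the 4 lists 0 members passed over all genes and 0 adjusted over the list alone. The other 11 lists did not pass, and adjusted over the list alone 1 gene, Mrpl58, passed among them. Median, mean and test differed in sign for the zona, EGF, cytosolic ribosome, oxidative phosphorylation and proteasome lists.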

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

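The tests with the array spread as a covariate and without the narrow arrays were chosen only after the result was seen. So were the lists after quantile normalisation and the test of a single knockout MII array. The limits of the tests on lists matched for brightness and on the genes next to Areg were fixed before those tests were run. The lists tested for brightness and Uba6 had themselves been picked from results already seen.

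The change from GV to MII differed between the genotypes for 4 gene lists in a test of that difference with camera at its preset correlation, and none of the 4 passed with an estimated correlation (adjusted p = 0.13, 0.29, 0.30 and 0.46 in the order they are named next) or after a further quantile normalisation (0.26, 0.15, 0.39 and 0.57). The median interaction was -0.26 for cyclin, CDK and APC/C genes, -0.33 for spindle and kinetochore genes, -0.22 for maternal-effect factors and -0.43 for DNA replication genes. With the spread covariate none passed and the cyclin median was -0.0029. Without the 4 arrays of narrowest spread none passed, the spindle median was -0.12 and the DNA replication median turned to 0.021. Single genes such as Kif11 (-1.03) and Mcm4 (-0.92) did not pass. Probe sets without a gene symbol, which the comparisons of genes left out, gave 1 that was higher in the knockout at MII, and 3 control probe sets for bacterial spike transcripts (dap 1.02, lys 1.03 and thr 1.36 on the log2 scale) were higher at MII in the knockout. Groups of 3 arrays were not searched for single deviating arrays.

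At MII the cyclin and spindle lists were lower in the knockout at the preset correlation (medians -0.11 and -0.27), calls that were lost with an estimated correlation (adjusted p = 0.19 and 0.30). By the limit fixed before the test, brightness may account for both lists, with the spindle list close to that limit. Among 10000 random lists of equal brightness the cyclin median lay at the 38.81th percentile and the spindle median at the 3.77th. The narrower spread of values on some arrays may also take part: with it as a covariate the cyclin median shrank to 0.458 of its size (-0.05, adjusted p = 0.39) and the spindle median to 0.663 (-0.18, adjusted p = 0.060). Without the 4 arrays of narrowest spread, which leaves 1 knockout MII array, the medians were -0.11 (adjusted p = 0.47) and 0.0057 (0.99), so the spindle list's direction was gone. Knockout MII 2 alone cannot be told apart from a genotype effect, since without it the medians were -0.042 and -0.076 (adjusted p = 0.11 for both), without knockout MII 3 the cyclin list did not pass (0.059) while the spindle list did (0.011), and without knockout MII 1 both passed (0.015 and 0.0016). A lower engagement of these mRNAs with ribosomes in oocytes without Areg stays open and was not tested apart from these.

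The 5 lists that fell from GV to MII in both genotypes were set against lists of equal brightness. For cytosolic ribosomal proteins the higher percentile of the genotypes was 0.01, for oxidative phosphorylation subunits 0, for mitochondrial ribosomal proteins 0 and for proteasome subunits 1.23, which argues against brightness as the whole cause. For zona and oocyte-secreted factors it was 28.22, so that list's fall may be that of bright genes at large. With the array spread as a covariate 10 of the 10 list tests still passed, which argues against a narrower spread as the whole cause. A selective loss of these mRNAs from polysomes and a loss of the transcripts themselves both stay open, as no total RNA was used here. RNA quality stays open too, though its controls moved in opposite directions. The 3' minus 5' signal of Actb fell with stage (0.36 to -1.17 in wild type, 0.05 to -0.77 in the knockout). That of Gapdh rose in wild type (2.00 to 3.23) and moved within its spread in the knockout (2.48 ± 0.75 to 2.71 ± 0.61, SD). The part of RNA quality in the falls was not tested.

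The 9 genes lower in the knockout at MII had 0.957 of their median difference with the spread covariate (-2.37 and -2.27). This ratio cannot decide on the array spread, since the genes were chosen for large differences with little variation within groups. The split of the MII arrays that set those of narrowest spread against the others gave 41 genes. Clybl (adjusted p = 0.046), Crnkl1 (0.017), Fbxw13 (0.046), Mrpl58 (0.017) and Uba6 (0.027) still passed, while Arid5b (-3.08 ± 0.44 without and -3.14 ± 0.48 with it, adjusted p = 0.071), Rbl2 (-2.80 ± 0.40 and -2.78 ± 0.43, 0.071), Tmem114 (-1.89 ± 0.28 and -1.91 ± 0.28, 0.061) and Uimc1 (-2.37 ± 0.31 and -2.27 ± 0.31, 0.056) did not, in a fit with fewer degrees of freedom. For Uba6, which lies 61 tested genes from Areg, a chromosome segment that travels with the targeted allele cannot be told apart from other sources, since 5 genes around Areg had an unadjusted p under 0.05 against a median of 4 over 14550 windows (percentile 58.7) and Uba6 itself lies outside the window. A strain variant in this mixed C57BL/6J and 129Sv background and an effect of Areg loss stay open and were not tested.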

How the results depend on the processing

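The fits with the array spread as a covariate, without the 4 arrays of narrowest spread and with the mean of both stages, and the lists under both scalings, were chosen after seeing the data. Over all alternatives the results for single named genes gave 5553 values in the same direction and on the same side of the threshold, 185 no longer past it, 38 newly past it and 68 in the other direction. The falls of 5 lists from GV to MII kept their direction in the 8 alternatives run for lists, which leave out no single array, and the zona and oocyte-secreted list no longer passed among bright genes alone (adjusted p = 0.081 in wild type and 0.17 in the knockout). Unless the construction of a fit shows it (fewer genes or arrays), the cause of a change was not tested.

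Genes differing at MII numbered 16 after quantile normalisation, 5 with trend and robust and 0 in a fit of the compared groups alone. Genes differing at GV numbered 1 among bright genes, 17 with array weights and 1 in the compared groups alone. The genotype difference averaged over both stages, which is a comparison of its own, gave 3 genes. In the knockout 1777 genes changed with stage with the spread covariate and 2978 without the narrow arrays. The interaction count was 2 without the narrow arrays. The median interaction of rising genes was -0.13 among bright genes, in the other direction, and that of falling genes was -0.24 with the spread covariate, past the threshold of limma's fry. The number of lists called at GV, at MII and in the interaction was 0 in each case with the estimated correlation, after quantile normalisation, among bright genes, with the spread covariate and without the narrow arrays.

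Leaving out 1 array at a time gave 2631 to 3728 genes for stage in wild type, 2882 to 5090 in the knockout, 0 to 3 for genotype at GV, 2 to 32 at MII and 0 to 1 for the interaction, and medians of -0.029 to 0.25 for rising genes, the lowest without wild-type MII 2, and -0.26 to -0.07 for falling genes. At GV the lowest and highest differences were -0.0065 and 0.30 for Areg, -0.14 and 0.17 for Tpx2, -0.0024 and 0.48 for Il7 and -0.23 and 0.27 for Ccnb1. At MII they were -0.21 and 0.074 for Areg, -0.17 and 0.29 for Tpx2, -0.088 and 0.52 for Il7 and -0.075 and 0.017 for Ccnb1. In the interaction they were -0.13 and 0.085 for Dazl, -0.30 and 0.31 for Il7, -0.16 and 0.30 for Tpx2, -0.29 and 0.22 for Ccnb1 and -0.10 and 0.34 for Mos.

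The other values in the opposite direction, none past the threshold, were these. After quantile normalisation: Areg with stage in the knockout -0.13, Ccnb1 at GV -0.064, and the interactions of Dazl 0.19, Il7 0.21 and Ccnb1 0.043. With the mean of probe sets: Egfr with stage in wild type 0.069. With array weights: Tpx2 at GV 0.12, Ccnb1 at GV -0.18, Areg at MII 0.017, and the interactions of Tpx2 -0.10, Ccnb1 0.17 and Mos -0.0089. With the spread covariate: Areg, Ereg and Lyz2 with stage in the knockout -0.42, -0.096 and -0.036, Tpx2 at GV 0.038, Ccnb1 at GV -0.021 and at MII 0.064, and the interactions of Tpx2 -0.033, Il7 0.34 and Ccnb1 0.085. Without the narrow arrays: Areg with stage in the knockout -0.037, Tpx2, Il7 and Ccnb1 at GV 0.17, -0.0024 and -0.23, Mos, Nuf2 and Kdm1b at MII -0.074, 0.0057 and 0.13, the interactions of Tpx2 -0.064, Il7 0.66, Ccnb1 0.18 and Mos -0.18, and the DNA replication list's interaction 0.021, while the spindle list's median at MII was 0.0057.

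With the replicate block, genes changed with stage numbered 3749 in wild type and 4967 in the knockout, and those for genotype at GV, at MII and in the interaction 0, 0 and 0. The series' design text speaks of 3 independent sample sets, and whether equal replicate numbers mark them is not given in the sources used here. Residuals of arrays with an equal number correlated over 0.1 in 10 of 18 pairs (0.14 to 0.19 for number 1, -0.12 to 0.12 for number 2 and -0.10 to 0.26 for number 3). Of 12 arrays 8 best matched an array of their own number, a hint from the data that does not settle a pairing.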

Other observations

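The exact permutation tests of the 6 genes fixed in advance were chosen only after the result was seen, and the other splits of the arrays were planned.

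Dazl was lower in the knockout at both stages without passing the test over all genes. Averaged over the stages its difference was -0.67, and in a two-sided exact permutation of the genotype labels within stages 1 of 200 splits, the real one, was as large (p = 0.005, the smallest possible, adjusted over the 6 genes p = 0.03), with 0.56 as the highest of the other splits. The values that prompted this test are the ones it used, so it is no independent evidence, and over all genes the adjusted p in the alternatives ran from 0.37 to 1.0 at GV and from 0.30 to 0.99 at MII. As a hypothesis, polysome-bound Dazl mRNA may be lower in oocytes without Areg at GV and MII alike. The other 5 genes gave no such result: 146 splits were as large for Areg (0.05, highest other 0.33), 189 for Tpx2 (0.03, 0.44), 93 for Il7 (0.20, 0.69), 188 for Ccnb1 (0.01, 0.27) and 44 for Mos (0.21, 0.42), so chance is not excluded for them.

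Other splits of the 6 arrays of a comparison number 10, which is too few for a share under 0.05. The real split gave 3574 genes for stage in wild type (highest other 1), 4672 in the knockout (0), 0 for genotype at GV (1) and 10 at MII (41). The split with 41 genes set wild-type MII 2, knockout MII 2 and knockout MII 3, the MII arrays with the narrowest spread of values, against the other 3, which points to a structure of the samples apart from genotype. For the lists called by camera at its preset correlation the real values were 5 in wild type (highest other 6), 5 in the knockout (6), 2 at GV (4) and 4 at MII (5), and the splits as large, the real one included, numbered 8, 6, 5 and 3. Every other split of GV and MII arrays mixes the stages unevenly and so keeps part of the stage difference. The list counts of such splits are therefore no measure of chance for the stage lists. For the interaction, the real count of 0 genes (highest other 5) cannot be tested this way, since any split gives at least as many. Of 100 splits of the genotype labels within stages, 13 gave as many lists (4, highest other 6), 38 as large an interaction of rising genes (0.10, highest other 0.41) and 25 of falling genes (0.18 in size, highest other 0.35), so chance is not excluded for these 3.

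Averaged over both stages, a comparison added after seeing the data, Uba6 (-2.97 ± 0.26, adjusted p = 0.0031), Arid5b (-3.34 ± 0.31, 0.0033) and Crnkl1 (-1.54 ± 0.15, 0.0035) were lower in the knockout. Of the 2656 probe sets without a symbol, 143 were higher and 142 lower at MII in wild type, and 396 and 192 in the knockout. The control probe sets of Actb (3' -3.06 and 5' -1.53) and Gapdh (5' -2.32) were lower at MII in wild type, as were Actb 3' (-2.16) and Gapdh 3' (-1.29) in the knockout. Probe sets of a single gene passed in opposite directions for 1 gene in wild type and 4 in the knockout.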
